A study of Homo sapiens with 12 samples.

How the data were processed

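The values analysed were the deposited intensities of 12 one-colour Agilent arrays, written per the file headers by Agilent Feature Extraction 11.5.1.1 for a design annotated on hg19. The processed signal is an intensity in arbitrary units, corrected for background per the file headers. It was turned into log2 here. The flag columns for saturation, outlier spots and signal well above background are of another kind and were used as the scanner software wrote them. The deposited matrix holds log2 values, a scale settled here by comparing it with the scanner intensities. Per the labels, the authors grew KG1a cells in IMDM with 20% FBS, irradiated them with a cobalt-60 teletherapy source, extracted RNA at 48 hr with an RNeasy kit, kept RNA with an integrity number above 9, and made Cy3-labelled cRNA by in vitro transcription. Groups were taken from the source descriptions, because the titles of all irradiated samples start with the same 8 Gy wording. The later part of each title names the same group as the source description. What the 8 Gy wording means for the dose was not resolved. Each array had 62976 spots, 58717 of them not controls, for 50599 probes of 60 bases.

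Spots with an outlier flag were left out, the remaining spots of a probe on an array were averaged as intensities, and the log2 of the mean was taken. The 75th percentile of log2 signal over the probes was subtracted from each array. Against the deposited matrix, the difference from these values had a median SD of 0.00325 across arrays over 21662 probes. Of the single differences of a probe on an array, 99.7% lay within 0.02 of that probe's mean difference. The matrix therefore follows the same scaling with a baseline taken from each probe. Which baseline the authors subtracted is unknown, and it cancels in contrasts, with higher matrix values standing for higher signal. The matrix columns had medians of -0.24, -0.30 and -0.22 (LiCl), -0.16, -0.20 and -0.22 (4Gy), -0.21, -0.12 and -0.14 (Li4Gy) and -0.23, -0.29 and -0.19 (Li8Gy).

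Of the probes, 45 without an unflagged spot on every array were dropped. Names came from the GRCh38.p14 gene reference, whose positions were not used: 28150 by transcript accession, 2615 by symbol and 619 by an older symbol, while 19170 kept the name in the file, which gave 50554 probes with 36373 names. A gene was represented by its probe of highest mean signal over the 12 arrays, and genes well above background on at least 3 of the 12 arrays were tested, which left 22007 genes, 13961 of them protein coding. Non-coding or unnamed genes were those the reference does not list as protein coding.

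Tests were made in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. A linear model with a mean per group was fitted to all 12 arrays with lmFit, contrasts were moderated with eBayes, and 8 residual degrees of freedom came from the arrays. The 4 contrasts were Li8Gy minus Li4Gy, Li4Gy minus LiCl, Li8Gy minus LiCl and Li4Gy minus 4Gy, and a gene was called at an adjusted p under 0.05 (Benjamini-Hochberg) within each contrast. Contrasts that share a group are not independent. The moderated F-test over the 4 groups gave the overall count. With 3 arrays per group the smallest exact p of a rank test would be 0.1, and none was used. Non-overlapping genes are those where all 3 values of a group lie on 1 side of the other group, which happens for 10% of genes by chance.

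Gene lists were fixed before the data were examined, as were the contrasts, the main settings and the rule for naming genes. The 26 lists were p53 target genes; DNA double-strand break repair and Fanconi genes; G1/S and S phase genes; G2/M and mitosis genes, replication-dependent histone genes, Wnt/beta-catenin target genes, hematopoietic stem and progenitor genes, myeloid granule genes, monocyte and macrophage genes, T, B and NK lymphoid markers, erythroid and megakaryocyte markers, stromal and fibroblast markers, type I interferon response genes, MHC class II genes, NF-kB and inflammatory cytokine genes, immediate early genes, BCL2 family and apoptosis genes, autophagy and lysosome genes, unfolded protein and integrated stress response genes, hypoxia and glycolysis genes, cholesterol synthesis genes, oxidative phosphorylation genes (nuclear), cytosolic ribosomal protein genes, NRF2 antioxidant genes, inositol and lithium target enzyme genes, and ribosome biogenesis and MYC target genes. Lists were tested with camera at its preset correlation of 0.01 and adjusted over all 104 list tests, then again with an estimated correlation per list and with fry. Members were counted with the adjustment over all genes and with an adjustment over the list alone.

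Genes named for a comparison were the 8 largest rises and 8 largest falls among called genes whose probe was well above background and not saturated on all 6 arrays, whose values did not overlap between the groups and whose symbol is a reference gene symbol not of a locus, long non-coding or small RNA type. Up to 4 called members per list were added, or up to 2 members where none was called, along with up to 2 genes per direction that were not well above background in the lower group. For those the fold change is a bound, in which each array of the lower group entered with its signal or with its detection floor, whichever was higher. The text gives part of the genes so chosen, and 2 of them are not reported here, although they stayed in the list tests and the counts. Where a gene had several probes, the range of their changes is given if signs differed.

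The steps were tested on simulated normal values with each gene's own mean and moderated SD and no group difference, except that known genes and the autophagy and lysosome list were shifted. Of genes shifted 2-fold, 59%, 60%, 59% and 64% were recovered in the 4 contrasts, and of those shifted 4-fold 86%, 84%, 98% and 94%, with 0 sign errors. The share of false genes among calls was 6.17%, 3.27%, 8.79% and 4.02%, and the shifted list was called in all 4 contrasts with 0 other lists. The simulated genes were independent of each other, so the simulation could not show false list calls that arise from correlation between members. In the data the estimated correlation was 0.48 for the histone list and 0.56 for the ribosomal protein list. Olfactory receptor probes (383) were taken as probes of genes not transcribed in this cell type, and RNAs without a poly(A) tail (227) were taken from the reference names.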

Results

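KG1a is an established human acute myelogenous leukemia cell line. Total RNA was taken at 48 hr from 4 groups of 3 samples each, and each sample was hybridised to its own one-colour Agilent array. The LiCl group received lithium chloride with no irradiation named, the 4Gy group received 4 Gy of cobalt-60 gamma rays, and the Li4Gy and Li8Gy groups were pre-treated with lithium chloride and then given 4 Gy or 8 Gy. The sample titles start with an 8 Gy wording beside the cell name for every irradiated group, and not for LiCl. The later part of each title names the same group as the source description. The doses rest on the source descriptions and treatment labels. What the 8 Gy wording stands for is not stated, and this doubt was not resolved. Cells with neither treatment and cells given 8 Gy alone were not analysed here. The labels do not state that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. Levels are log2 signal minus the array's 75th percentile, given as mean ± SD (n = 3). Changes are log2 fold changes ± SE from limma, with Benjamini-Hochberg adjustment over 22007 genes.

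On the 3 arrays of the 4Gy group 59.4% to 64.5% of spots were well above background, and on the other 9 arrays at most 54.6%. No spot was saturated, and the 75th percentile signal ran from 207 units on Li4Gy replicate 2 to 398 units on 4Gy replicate 2. Pearson correlations between the arrays of a group, taken over genes, ranged from 0.984 to 0.995. The LiCl arrays filled slide 1, the 4Gy arrays slide 2, and the Li4Gy and Li8Gy arrays slide 3. Slide and group could therefore not be told apart except in the comparison of Li8Gy with Li4Gy, where both groups lay on 1 slide. Li4Gy replicate 2 lay apart from the other 11 arrays on the second principal component, at -56.89, and counts without it are given below. In the overall comparison of 4 groups by an F-test 8627 genes varied.

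The first comparison, Li8Gy against Li4Gy, asked what the higher radiation dose changed in lithium-treated cells. S100P, a calcium-binding protein gene, rose 2.73-fold, from 1.68 ± 0.24 to 3.12 ± 0.05 (log2 change 1.45 ± 0.14, adjusted p = 0.00958). ASNS, which encodes asparagine synthetase, rose 1.66-fold (0.73 ± 0.09, adjusted p = 0.0210), and PSAT1, an enzyme of serine synthesis, rose by 0.72 ± 0.10 (adjusted p = 0.0336). The glycine transporter gene SLC6A9 (1.44 ± 0.18, adjusted p = 0.0258) and the cystine transporter gene SLC7A11 (0.61 ± 0.09, adjusted p = 0.0402) rose. The transcriptional repressor gene JDP2 (1.07 ± 0.15, adjusted p = 0.0308) and ULBP1, a ligand of the natural killer cell receptor NKG2D (1.02 ± 0.12, adjusted p = 0.0210), also rose. MFAP4, a microfibril-associated protein gene, rose by 0.76 ± 0.11 (adjusted p = 0.0336). PPP1R14A, which encodes an inhibitor of myosin phosphatase, had the largest fall among the named genes, at -2.13 ± 0.26 (adjusted p = 0.0244).

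Further falls were measured for the homeobox gene NKX1-2 (-1.55 ± 0.24, adjusted p = 0.0484), CCDC78 (-1.49 ± 0.21, adjusted p = 0.0336), YJEFN3 (-1.37 ± 0.16, adjusted p = 0.0210) and ABHD1 (-0.82 ± 0.11, adjusted p = 0.0273). OSCAR, an immunoglobulin-like receptor gene, fell on its brighter probe (-1.19 ± 0.17, adjusted p = 0.0336), while its other probe read 0.62. The pseudogene TPTE2P6 was at least 1.70-fold lower in Li8Gy, where its probe was not well above background on any array (adjusted p = 0.00958). By the hg19 positions in the file headers and probe annotation, the S100P probe covers chromosome 4, 6698819 to 6698878, the JDP2 probe chromosome 14, 75937082 to 75937141, and the ASNS probe chromosome 7, 97481461 to 97481520. Exon and UTR annotation of that build was not analysed here.

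Replication-dependent histone genes, which encode the core and linker histones of newly made chromatin, fell as a list, with a median of -0.64 and 52 of 54 members negative (adjusted p = 6.59e-25). The adjusted p was 0.286 with an estimated correlation, and without Li4Gy replicate 2, whose histone mean of 1.80 lay above 1.14 and 1.17 in the other Li4Gy arrays, the median was -0.43. Of the 54 members 1 fell, H2BC3 (-0.74 ± 0.09, adjusted p = 0.0258), 0 rose and 53 did not pass, and 35 fell when adjusted over the list alone. Probes of histone paralogs can share sequence, so single histone genes are uncertain. Unfolded protein and integrated stress response genes rose as a list, with a median of 0.13 (adjusted p = 7.69e-08 and adjusted p = 0.286 with an estimated correlation). In that list 3 of 41 members rose, ASNS, PSAT1 and SLC7A11, 0 fell and 38 did not pass, and 9 rose when adjusted over the list alone. Without Li4Gy replicate 2 its median was 0.10 and ASNS (0.71, adjusted p = 0.0502), PSAT1 (0.71, adjusted p = 0.0842) and SLC7A11 (0.54, adjusted p = 0.0842) kept similar values but did not pass. G2/M and mitosis genes rose as a list with a median of 0.16 and 50 of 56 members positive (adjusted p = 9.08e-08 and adjusted p = 0.349 with an estimated correlation). The median was 0.07 without Li4Gy replicate 2. None of the 56 passed singly, and the values of TOP2A, a topoisomerase, and CTCF, a chromatin insulator protein, were 0.70 ± 0.37 and 0.37 ± 0.27, against 0.17 and -0.02 without that array.

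The immediate early genes (median 0.12 over 23 genes, adjusted p = 0.00746 and adjusted p = 0.293 with an estimated correlation) had 0 members past the test. DNA double-strand break repair and Fanconi genes had a median of 0.07 over 40 genes (adjusted p = 0.0171 and adjusted p = 0.578 with an estimated correlation), with 0 members past the test. Type I interferon response genes had a median of 0.05 over 44 genes (adjusted p = 0.0171 and adjusted p = 0.293 with an estimated correlation). In that list 0 members passed the test over all genes and 1 rose when adjusted over the list alone, and XAF1, an interferon-induced apoptosis factor, read 0.61 ± 0.11 (adjusted p = 0.0790). Hematopoietic stem and progenitor genes (median 0.08 over 26 genes, adjusted p = 0.0344 and adjusted p = 0.434 with an estimated correlation) and BCL2 family and apoptosis genes (median 0.08 over 36 genes, adjusted p = 0.0380 and adjusted p = 0.547 with an estimated correlation) had 0 members past the test. The calls of these 5 lists ended under other settings or when single arrays were left out, and without Li4Gy replicate 2 the repair, stem and progenitor and BCL2 lists had an adjusted p of 0.309, 0.189 and 0.433.

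In all, 31 genes changed between Li8Gy and Li4Gy, 10 higher and 21 lower, and 5 and 17 of these by at least 2-fold. At an unadjusted p under 0.05 there were 2261 genes, and in 13.4% of genes the groups did not overlap, against 10% by chance. The count was 6 without Li4Gy replicate 2, with S100P (adjusted p = 0.0114), PPP1R14A (adjusted p = 0.0427) and TPTE2P6 (adjusted p = 0.0278) still past the test. It was 151 without Li4Gy replicate 1 and 7 to 12 without any other single array of these groups. Fitted on these 6 arrays of 1 slide alone, limma called 0 genes, with 1479 at an unadjusted p under 0.05.

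**Figure D1:**
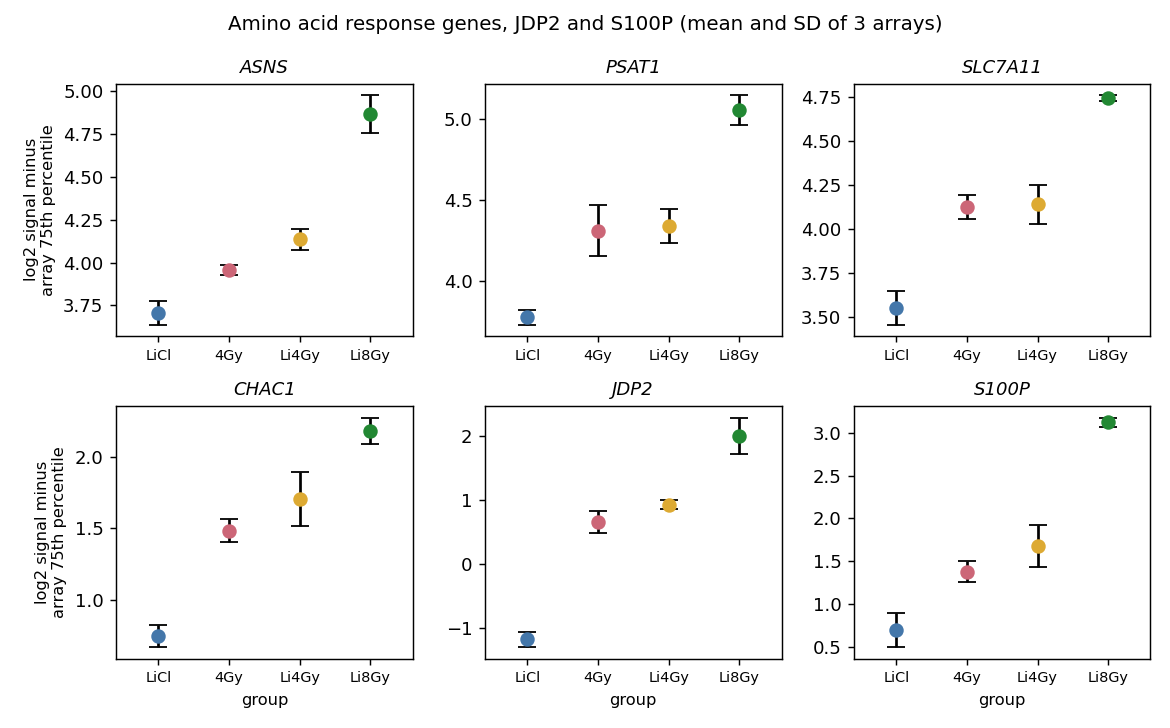
Levels of ASNS, PSAT1, SLC7A11, CHAC1, JDP2 and S100P in the 4 groups, as log2 signal minus the array's 75th percentile on the vertical axes, with points for the mean and bars for the SD of 3 arrays. The S100P mean was 0.69 in LiCl, 1.37 in 4Gy, 1.68 in Li4Gy and 3.12 in Li8Gy.

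The comparison of Li8Gy with LiCl asked what 8 Gy changed in lithium-treated cells. JDP2 rose 9.05-fold, from -1.18 ± 0.12 to 2.00 ± 0.28 (adjusted p = 2.19e-05), SLC6A9 rose 7.76-fold (adjusted p = 0.000124) and S100P rose 5.39-fold (adjusted p = 0.000104). ULBP1 rose by 1.84 ± 0.12 (adjusted p = 0.000186), CTSG, which encodes the neutrophil granule protease cathepsin G, rose by 1.78 ± 0.13 (adjusted p = 0.000303), and WARS1, the cytosolic tryptophanyl-tRNA synthetase gene, rose by 1.44 ± 0.12 (adjusted p = 0.000539). The 8 largest falls among the named genes were all of histone genes, led by H2BC7 at -2.23 ± 0.26 (adjusted p = 0.00217), H1-4 at -1.99 ± 0.27 (adjusted p = 0.00423) and H1-3 at -1.98 ± 0.27 (adjusted p = 0.00437). Cyclin E2, CCNE2 (-1.32 ± 0.16, adjusted p = 0.00233), and cyclin E1, CCNE1 (-0.95 ± 0.08, adjusted p = 0.000600), which drive entry into S phase, fell.

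As a list, replication-dependent histone genes fell with a median of -1.13 (adjusted p = 7.31e-33 and adjusted p = 0.286 with an estimated correlation). Of 54 members 40 fell, 1 rose and 13 did not pass. When adjusted over the list alone 45 fell and 1 rose. The mean level over the list was 1.81 ± 0.04 in LiCl and 0.74 ± 0.01 in Li8Gy. G1/S and S phase genes fell with a median of -0.32 (adjusted p = 5.13e-12 and adjusted p = 0.286 with an estimated correlation). Of 52 members 12 fell, 0 rose and 40 did not pass, and 25 fell when adjusted over the list alone, with CLSPN, a replication checkpoint gene, at -0.88 ± 0.16 (adjusted p = 0.0147). RRM2, a ribonucleotide reductase subunit, fell on its brightest probe (-0.69 ± 0.18, adjusted p = 0.0487), with its 3 probes between -0.69 and 0.02. G2/M and mitosis genes rose with a median of 0.16 and 4 of 56 members past the test, all higher, and also 4 when adjusted over the list alone (adjusted p = 0.00113 and adjusted p = 0.547 with an estimated correlation). These were the ubiquitin-conjugating enzyme UBE2C (0.70 ± 0.10), cyclin B2, CCNB2 (0.51 ± 0.09), the spindle protein TACC3 (0.48 ± 0.12) and CDCA2 (0.47 ± 0.10).

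**Figure D2:**
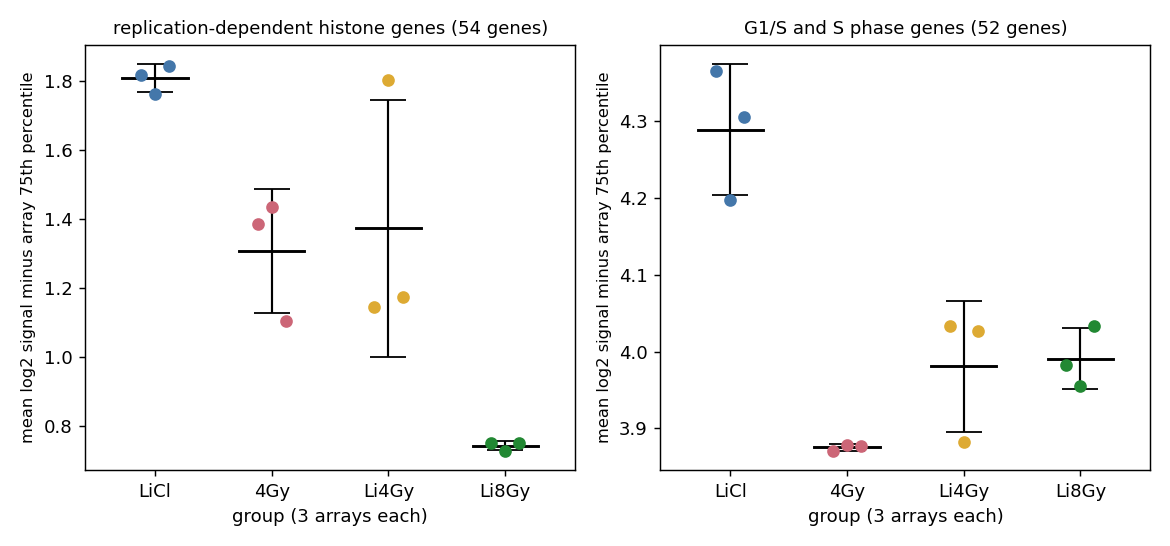
Mean log2 signal minus the array's 75th percentile over 54 replication-dependent histone genes and over 52 G1/S and S phase genes, with a point for each array and lines and bars for the mean and SD of 3 arrays. The histone mean was 1.81 in LiCl, 1.31 in 4Gy, 1.37 in Li4Gy with replicate 2 at 1.80, and 0.74 in Li8Gy.

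In the unfolded protein and integrated stress response list 13 of 41 members rose, 1 fell and 27 did not pass, and 15 rose and 2 fell when adjusted over the list alone. Its median was 0.15 (adjusted p = 0.000876 and adjusted p = 0.286 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, rose by 1.44 ± 0.11 (adjusted p = 0.000304), PSAT1 by 1.28 ± 0.10 (adjusted p = 0.000416), SLC7A11 by 1.19 ± 0.09 and ASNS by 1.16 ± 0.09 (both adjusted p = 0.000303). Nuclear oxidative phosphorylation genes fell with a median of -0.16 and 47 of 52 members negative (adjusted p = 1.01e-07 and adjusted p = 0.293 with an estimated correlation). Of these 4 fell, 0 rose and 48 did not pass, and 5 fell when adjusted over the list alone. Among them were the complex I gene NDUFB6 at -0.54 ± 0.12 (adjusted p = 0.0270) and the ATP synthase gene ATP5MC1 at -0.43 ± 0.10 (adjusted p = 0.0271). Repair genes fell with a median of -0.08 (adjusted p = 0.0119 and adjusted p = 0.547 with an estimated correlation). Of 40 repair genes 2 fell, as also when adjusted over the list alone, 0 rose and 38 did not pass. These were RAD51C, of homologous recombination (-0.69 ± 0.08, adjusted p = 0.00176), and the damage kinase gene ATM (-0.52 ± 0.12, adjusted p = 0.0327), whose 3 probes ran from -0.52 to 0.03.

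Myeloid granule genes rose with a median of 0.19 (adjusted p = 0.0380 and adjusted p = 0.293 with an estimated correlation). In it 3 of 14 members rose, CTSG, the protease inhibitor CST7 (1.21 ± 0.20, adjusted p = 0.00853) and the myeloid transcription factor CEBPA (0.42 ± 0.09, adjusted p = 0.0297). None fell, 11 did not pass, and 4 rose when adjusted over the list alone. MHC class II genes rose with a median of 0.39 (adjusted p = 0.00875 and adjusted p = 0.286 with an estimated correlation). Of 11 members 1 rose, HLA-DMB (1.15 ± 0.29, adjusted p = 0.0449), whose probe was well above background on 2 of 3 LiCl arrays, 0 fell and 10 did not pass. When adjusted over the list alone 2 rose. The list was dim, with a mean level of -2.78 ± 0.14 in LiCl, and over all genes the median change was 0.27 in the lowest 10% of mean signal and -0.02 in the highest 10%. Type I interferon response genes fell with a median of -0.13 (adjusted p = 0.0380 and adjusted p = 0.350 with an estimated correlation). Of its 44 members 2 rose, XAF1 (0.88 ± 0.11, adjusted p = 0.00284) and OASL, of the oligoadenylate synthetase family (0.64 ± 0.16, adjusted p = 0.0413), and 1 fell, the antiviral gene MX1 (-0.57 ± 0.13, adjusted p = 0.0354), with the same counts when adjusted over the list alone. The other 41 did not pass. VWA2 was at least 1.99-fold higher and GDAP1 at least 1.72-fold lower in Li8Gy than in LiCl (adjusted p = 0.00807 and 0.00782).

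In all, 1387 genes changed between Li8Gy and LiCl, 752 higher and 635 lower, 193 and 88 of these by at least 2-fold, with non-overlapping groups in 29.7% of genes against 10% by chance. Slide and group cannot be told apart here, and limma called 328 genes when fitted on these 6 arrays alone. The repair, myeloid granule, interferon, MHC class II and G2/M calls each ended under at least 1 other setting, the G2/M call with fry (adjusted p = 0.0581). Leaving out single arrays of these groups gave 574 (without LiCl replicate 1) to 966 genes (without LiCl replicate 2).

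The comparison of Li4Gy with LiCl asked what 4 Gy changed in lithium-treated cells. JDP2 rose 4.30-fold, to 0.92 ± 0.07 (adjusted p = 0.000679), and PPP1R14A rose by 2.36 ± 0.26 (adjusted p = 0.00349). Other rises were those of SPSB4, of a family of ubiquitin ligase adaptors (2.34 ± 0.38, adjusted p = 0.00787), the glycosyltransferase gene A4GALT (1.88 ± 0.36, adjusted p = 0.0143), NKX1-2 (1.82 ± 0.24, adjusted p = 0.00403) and CTSG (2.30-fold, adjusted p = 0.00349). DOCK3, an exchange factor for small GTPases, rose by 2.64 ± 0.75 (adjusted p = 0.0471), a call that ended without Li4Gy replicate 2 (1.65, adjusted p = 0.0801). Falls among the named genes were led by H2BC7 (-1.44 ± 0.26, adjusted p = 0.0113), E2F7, a repressor of cell cycle genes (-1.22 ± 0.11, adjusted p = 0.00270), and CCNE2 (-1.06 ± 0.16, adjusted p = 0.00614). The interferon-induced chemokine CXCL10 fell less (-0.96 ± 0.21, adjusted p = 0.0216). VWA2 was at least 2.40-fold higher and EPM2A, the glycogen phosphatase laforin, at least 1.58-fold lower (adjusted p = 0.00392 and 0.0241).

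G1/S and S phase genes fell as a list, with a median of -0.33 (adjusted p = 2.45e-12 and adjusted p = 0.286 with an estimated correlation). Of 52 members 16 fell, 0 rose and 36 did not pass, and 27 fell when adjusted over the list alone, with CLSPN at -0.70 ± 0.16 (adjusted p = 0.0260) and CASP8AP2, a regulator of histone gene transcription, at -0.68 ± 0.16 (adjusted p = 0.0251). RRM2 fell on its brightest probe (-0.88 ± 0.18, adjusted p = 0.0168), with its 3 probes between -0.88 and 0.26. Replication-dependent histone genes fell with a median of -0.50 (adjusted p = 2.81e-10 and adjusted p = 0.435 with an estimated correlation). Of 54 members 6 fell, 2 rose and 46 did not pass, and 26 fell and 2 rose when adjusted over the list alone. Without Li4Gy replicate 2 the median was -0.73, and 35 fell and 1 rose. H2AC11 (-0.87 ± 0.22, adjusted p = 0.0308) was among those that fell, and H3C12 (0.74 ± 0.09, adjusted p = 0.00391) among those that rose. Repair genes fell with a median of -0.17 (adjusted p = 5.27e-05 and adjusted p = 0.364 with an estimated correlation), with RAD51C (-0.57 ± 0.08, adjusted p = 0.00443), the end resection gene RBBP8 (-0.56 ± 0.12, adjusted p = 0.0192) and FANCI of the Fanconi pathway (-0.43 ± 0.09, adjusted p = 0.0190) lower. Those were 3 of 40, as also when adjusted over the list alone, with 0 higher and 37 not past the test.

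Oxidative phosphorylation genes fell with a median of -0.15 (adjusted p = 5.51e-05 and adjusted p = 0.387 with an estimated correlation), with NDUFB6 (-0.45 ± 0.12) and NDUFAB1 (-0.44 ± 0.10) lower. The other 50 of 52 did not pass, 0 rose, and 0 passed when adjusted over the list alone. Type I interferon response genes fell with a median of -0.15 (adjusted p = 0.00123 and adjusted p = 0.286 with an estimated correlation). Of 44 members 6 fell, 1 rose and 37 did not pass, and 6 fell and 2 rose when adjusted over the list alone, with MX1 at -0.62 ± 0.13 (adjusted p = 0.0207) and OASL at 0.55 ± 0.16 (adjusted p = 0.0467). Its median was -0.10 without Li4Gy replicate 2, with 4 lower and 0 higher. NF-kB and inflammatory cytokine genes fell with a median of -0.07 (adjusted p = 0.0380 and adjusted p = 0.387 with an estimated correlation). Of 29 members 4 fell, as also when adjusted over the list alone, 0 rose and 25 did not pass, and the NF-kB inhibitor gene NFKBIA was at -0.48 ± 0.10 (adjusted p = 0.0187) and the chemokine gene CXCL2 at -0.69 ± 0.16 (adjusted p = 0.0241). T, B and NK lymphoid markers rose with a median of 0.28 (adjusted p = 0.0490 and adjusted p = 0.443 with an estimated correlation). Of 26 members 5 rose, 1 fell and 20 did not pass, and 10 rose and 1 fell when adjusted over the list alone, with CD4 at 1.22 ± 0.30 (adjusted p = 0.0310) and GZMB, the granzyme B gene, at 0.71 ± 0.14 (adjusted p = 0.0171). Without Li4Gy replicate 2 there were 3 higher and 0 lower. The probe of LCK, 1 of the 5, was not well above background on any array of these groups. Dim genes moved the same way as the lymphoid markers, with a median of 0.53 in the lowest 10% of mean signal against -0.03 in the highest 10%.

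In all, 2733 genes changed between Li4Gy and LiCl, 1996 higher and 737 lower, 636 and 19 of these by at least 2-fold, with non-overlapping groups in 32.3% of genes against 10% by chance. Of the 1996 higher, 1123 were non-coding or unnamed. Slide and group cannot be told apart here, limma called 32 genes when fitted on these 6 arrays alone, and the NF-kB and lymphoid calls ended under other settings. The histone and oxidative phosphorylation calls ended with fry (adjusted p = 0.0920 and 0.0581). Without Li4Gy replicate 2 the NF-kB and lymphoid lists had an adjusted p of 0.1202 and 0.0646, and the calls of OASL (0.43, adjusted p = 0.124), CXCL2 (-0.68, adjusted p = 0.0595) and NDUFB6 (-0.41, adjusted p = 0.0904) ended. The count was 1539 without Li4Gy replicate 2, 1048 without LiCl replicate 1, 1472 without LiCl replicate 2, 1753 without LiCl replicate 3 and 5257 after median centring. At least 2-fold changes numbered 341 higher and 32 lower without Li4Gy replicate 2, and 276 and 226 after median centring. With normexp background correction and quantile normalization they numbered 86 and 1.

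The comparison of Li4Gy with 4Gy asked what lithium pre-treatment changed in cells given 4 Gy. CCL4 and CCL3, which encode inflammatory chemokines, rose 4.34-fold (2.12 ± 0.28, adjusted p = 0.00111) and 4.05-fold (2.02 ± 0.27, adjusted p = 0.00102). SLC35F3, a solute carrier gene (1.29 ± 0.15, adjusted p = 0.000497), and the epithelial membrane protein gene EMP1 (1.19 ± 0.18, adjusted p = 0.00214) rose. The 8 largest falls among the named genes were those of the pseudogene NACA4P (-2.26 ± 0.26, adjusted p = 0.000497), the golgin family gene GOLGA6C (-2.07 ± 0.23, adjusted p = 0.000482), SLC23A3, a solute carrier gene whose 2 probes read -1.93 and 0.51 (SE 0.27, adjusted p = 0.00130, for the former), the sterol transporter ABCG5 (-2.29 ± 0.21, adjusted p = 0.000196), KRTAP6-2, a hair keratin-associated protein (-2.24 ± 0.10, adjusted p = 1.18e-05), the lipase gene LIPM (-2.03 ± 0.19, adjusted p = 0.000223), the calcium channel gene TRPV5 (-1.97 ± 0.31, adjusted p = 0.00233) and the nicotinic receptor subunit CHRNB3 (-1.89 ± 0.11, adjusted p = 4.21e-05). NUGGC was at least 4.24-fold lower and TAT, of tyrosine catabolism, at least 1.84-fold higher in Li4Gy (adjusted p = 0.00547 and 0.0140).

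Probes of olfactory receptors, which serve smell, were well above background for 30.2% ± 4.82 (SD, n = 3) of 383 probes on the 4Gy arrays and for 10.1% ± 1.88 on the other 9. Beside them the stromal chemokine gene CXCL12 fell (-1.34 ± 0.19, adjusted p = 0.00154), although neither the stromal nor the erythroid list was called (adjusted p = 0.630 and 0.390). The median change over genes ran from -1.21 in the lowest 10% of mean signal to 0.20 in the highest 10%. Of the falls named above, ABCG5, SLC23A3, LIPM, CHRNB3, KRTAP6-2 and TRPV5 were dim in Li4Gy, with means from -3.82 to -2.51. NACA4P and GOLGA6C were brighter, at 0.14 and -0.17. Lithium and the shift of dim probes on the 4Gy slide could not be told apart as a source of these falls.

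**Figure D3:**
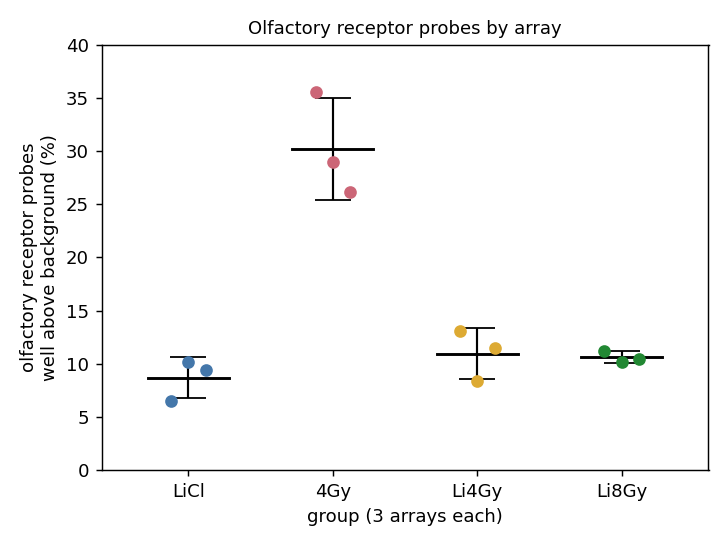
Percent of 383 olfactory receptor probes well above background on each of the 12 arrays, with lines and bars for the mean and SD of 3 arrays per group. The 4Gy arrays lie between 26.1% and 35.5% and the other 9 arrays between 6.53% and 13.1%.

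MHC class II genes fell in Li4Gy as a list, with a median of -0.70 (adjusted p = 0.0380 and adjusted p = 0.286 with an estimated correlation). Of its members 5 of 11 fell, 0 rose and 6 did not pass, and 6 fell when adjusted over the list alone. Without Li4Gy replicate 2 the call ended (median -0.46, adjusted p = 0.0724). The list was dim, with a mean level of -1.74 ± 0.08 in 4Gy and -2.32 ± 0.04 in Li4Gy, and it was not compared with genes of like signal. HLA-DQB1 fell by 1.53 on the log2 scale (SE 0.16, adjusted p = 0.000353) and HLA-DPA1 by 0.80 (SE 0.14, adjusted p = 0.00386). Cytosolic ribosomal protein genes rose with a median of 0.35 (adjusted p = 8.74e-13 and adjusted p = 0.433 with an estimated correlation). Of these 21 of 58 rose, 0 fell and 37 did not pass, and 43 rose when adjusted over the list alone, among them RPL3 (0.61 ± 0.14) and RPL8 (0.51 ± 0.10). This list's median was 0.26 and 8 rose without Li4Gy replicate 2. Oxidative phosphorylation genes rose with a median of 0.23 (adjusted p = 5.45e-07 and adjusted p = 0.295 with an estimated correlation). In this list 11 of 52 rose, 0 fell and 41 did not pass, and 13 rose when adjusted over the list alone, among them UQCRC1 of complex III (0.57 ± 0.11). Ribosome biogenesis and MYC target genes rose with a median of 0.24 (adjusted p = 2.57e-06 and adjusted p = 0.286 with an estimated correlation). Among them 9 of 40 rose, 0 fell and 31 did not pass, and 12 rose when adjusted over the list alone, among them the nuclear import gene IPO4 (0.66 ± 0.12) and the pyrimidine synthesis gene CAD (0.57 ± 0.13). G2/M and mitosis genes rose with a median of 0.20 (adjusted p = 5.02e-05 and adjusted p = 0.435 with an estimated correlation). There 6 of 56 rose, 0 fell and 50 did not pass, and 0 passed when adjusted over the list alone, among them the mitotic kinase PLK1 (0.43 ± 0.11).

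The remaining 6 called lists rose by medians of 0.09 to 0.18. Bright genes rose in this comparison whatever their list. The median change over all genes was 0.20 in the highest 10% of mean signal and 0.15 in the next 10%. The lists that rose here were not compared with genes of like signal. How much of their rises came from this shift of bright genes was not tested, so the rises cannot be assigned to lithium. In the unfolded protein and integrated stress response list (adjusted p = 0.00438 and adjusted p = 0.293 with an estimated correlation) 6 of 41 rose and 1 fell, as also when adjusted over the list alone, with the transcription factor ATF5 at 0.57 ± 0.10. The autophagy and lysosome list (adjusted p = 0.00632 and adjusted p = 0.286 with an estimated correlation) had 5 of 42 higher and 1 lower, and 5 and 0 when adjusted over the list alone, with the cargo receptor SQSTM1 at 0.49 ± 0.12. The hypoxia and glycolysis list (adjusted p = 0.00856 and adjusted p = 0.387 with an estimated correlation) had 5 of 36 higher and 0 lower, and 2 and 0 when adjusted over the list alone, with GAPDH at 0.52 ± 0.13. The repair list (adjusted p = 0.00581 and adjusted p = 0.506 with an estimated correlation) had 4 of 40 higher and 1 lower, and 0 past the test when adjusted over the list alone, with XRCC6 of end joining at 0.44 ± 0.10 and the ligase LIG4 at -1.14 ± 0.29. The G1/S and S phase list (adjusted p = 0.0129 and adjusted p = 0.603 with an estimated correlation) had 2 of 52 higher and 1 lower, and 0 when adjusted over the list alone, with the helicase subunit MCM5 at 0.47 ± 0.14. The NRF2 antioxidant list (adjusted p = 0.0171 and adjusted p = 0.286 with an estimated correlation) had 4 of 26 higher and 0 lower, as also when adjusted over the list alone, with the ferritin light chain FTL at 0.58 ± 0.10. Without Li4Gy replicate 2 the NRF2 call ended (adjusted p = 0.0706, 3 higher and 2 lower), the repair and S phase medians were 0.18 and 0.14, and LIG4 (-0.88, adjusted p = 0.0529) and MCM5 (0.36, adjusted p = 0.0894) did not pass. The autophagy and lysosome list then had 8 higher and 0 lower, and the repair list 7 higher and 0 lower.

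In all, 4542 genes changed between Li4Gy and 4Gy, 1481 higher and 3061 lower, 14 and 2060 of these by at least 2-fold, with 2011 of the 3061 non-coding or unnamed and non-overlapping groups in 40.3% of genes against 10% by chance. Slide and group cannot be told apart here. With quantile normalization 2901 genes and 0 lists were called by camera, with 1 list at an unadjusted p under 0.05, while the medians of the ribosomal protein and the G1/S and S phase lists turned negative, at -0.02 and -0.05. With normexp background correction and quantile normalization 2721 genes and 0 lists were called, with 3 lists at an unadjusted p under 0.05, and the same 2 medians were -0.01 and -0.05. Without 4Gy replicate 1 the count was 2061, and without 4Gy replicate 3 it was 2710. At least 2-fold changes numbered 699 higher and 1048 lower after median centring, and 134 and 1039 with quantile normalization. With normexp background correction and quantile normalization they numbered 1 and 81.

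Some lists that camera did not call still had members past the test. In Li4Gy against LiCl 8 of 41 unfolded protein and integrated stress response genes rose, 1 fell and 32 did not pass. The median was 0.07 (adjusted p = 0.446 with camera and 0.0250 with fry). CHAC1 was among those higher (0.96 ± 0.11, adjusted p = 0.00371). Without Li4Gy replicate 2 there were 5 higher and 1 lower. In Li4Gy against 4Gy 5 of 36 BCL2 list genes rose and 1 fell, and 4 of 29 NF-kB list genes rose and 2 fell. In the order Li8Gy against Li4Gy, Li4Gy against LiCl, Li8Gy against LiCl and Li4Gy against 4Gy, the counts higher among 30 p53 target genes were 0, 2, 2 and 1, with 0 lower in each. The list was not called in Li4Gy against 4Gy (median 0.06, adjusted p = 0.166), but it was without Li4Gy replicate 2 (median 0.21, adjusted p = 0.0308), as was the BCL2 list (median 0.10 and then 0.18, adjusted p = 0.143 and then 0.0308). Myeloid granule genes in Li8Gy against Li4Gy likewise went from an adjusted p of 0.0599 to 0.0114 (median 0.06 and then 0.05). The p53 target and stress gene SESN2 was higher in Li8Gy than in LiCl (1.05 ± 0.13, adjusted p = 0.00345), as was PLK2 (0.54 ± 0.12, adjusted p = 0.0289). Among 21 Wnt/beta-catenin target genes, relevant to lithium as an inhibitor of GSK3, the counts higher were 0, 2, 1 and 1, with 0 lower. Only the last of these comparisons differed in lithium, and it differed in slide too. There NKD2 was higher on its brighter probe (0.39), while its other probe read -0.46. CDX1 was higher in Li4Gy than in LiCl, which both received lithium (0.78 ± 0.17, adjusted p = 0.0226, and 0.61 with adjusted p = 0.0530 without Li4Gy replicate 2). The other CDX1 probe read 0.23. Among 18 inositol and lithium target enzyme genes 0 passed in any comparison, with list medians of 0.04, -0.05, -0.05 and 0.12. Monocyte and macrophage genes (26 tested) had 0, 5, 4 and 1 higher and 3 lower in the last comparison, with the chemokine receptor CCR2 at 0.83 ± 0.15 in Li8Gy against LiCl (adjusted p = 0.0145). Without Li4Gy replicate 2 there were 2 higher and 1 lower in Li4Gy against LiCl. Erythroid and megakaryocyte markers (22 tested) had 0, 3, 2 and 2 higher and 5 lower in the last comparison. Without Li4Gy replicate 2 these markers had 1 higher in Li4Gy against LiCl, and 1 higher and 8 lower in Li4Gy against 4Gy. Stromal and fibroblast markers (12 tested) had 0, 0, 0 and 1 higher and 0, 1, 1 and 2 lower. Cholesterol synthesis genes (25 tested) had 0 members past the test except 1 higher in the last comparison, SREBF2 (0.32 ± 0.09, adjusted p = 0.0360, and 0.27 with adjusted p = 0.0697 without Li4Gy replicate 2).

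Over the 4 comparisons 8, 7, 9 and 11 of 26 lists were called by camera with its preset correlation, 7, 1, 4 and 10 of them upward, and the adjusted p of the others ran from 0.0599 to 0.947. With an estimated correlation 0 lists held in any comparison, with 3, 3, 6 and 4 at an unadjusted p under 0.05, and fry called 2, 9, 6 and 8. In every called list the median, the mean and the test had 1 sign. Among those not called they differed for 25 list results, as in Wnt/beta-catenin target genes for Li8Gy against LiCl (median 0.09, mean -0.02). Centring arrays on the median instead of the 75th percentile moved the median change of all genes to 0.12, -0.26, -0.13 and 0.51, so that the changes above are relative to the brighter part of each array. The calls were then 36.4%, 14.3%, 19.5% and 86.4% upward against 32.3%, 73.0%, 54.2% and 32.6%. With normexp background correction and quantile normalization the upward shares were 28.9%, 56.4%, 43.9% and 33.0%.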

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

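A first part weighs the receptor-probe signal of the 4Gy arrays, and its tests on negative controls, genomic DNA and the slide were chosen only after the result was seen. On average 30.2% of olfactory receptor probes were well above background on the 4Gy arrays, against 10.1% ± 1.88 (SD) on the other 9. Optical background would have raised the negative controls as well, and their gap was -0.474. If genomic DNA in the 4Gy samples gave this signal, most receptor probes should be brighter there than on any other array. The share with a 4Gy mean above every other array was 36.6%, which falls short of that. It was at most 11.7% for any 3 of the other arrays. Priming that needs A-rich stretches can leave probes out, so genomic DNA was not settled. The slide or the absence of lithium might equally have given the receptor-probe signal, since 1 group lay on that slide.

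In a second part on Li4Gy replicate 2, the test on spike RNA was chosen only after the result was seen, and the test on an unirradiated sample was set before. Its spike-in signal lay 5.26 above its 75th percentile, against 3.37 to 3.84 on the other 11 arrays, a gap of 1.42. Less sample RNA per spike-in may have given this gap. The array's low 75th percentile of 207 units is part of the value, and the 75th percentile was subtracted from each array. The gap alone therefore does not explain why this array stood apart. A sample that was not irradiated could also have been hybridised, but its position between LiCl and Li8Gy over 1933 genes was 0.953, with the other Li4Gy arrays at 0.853 and 0.854, and because no LiCl array lay on that slide this was not settled. Its histone mean of 1.80 stood near the LiCl arrays, so this array likely enlarged the histone fall of Li8Gy against Li4Gy, whose median went from -0.64 to -0.43 without it.

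The third part weighs the histone fall, and its tests on GC content and on S phase were chosen only after the result was seen, while the tests on RNAs without a poly(A) tail were set before. A bias by GC content is not likely, since genes matched for the histones' 53.3% GC had a median of 0.0654 for Li8Gy against LiCl, against -1.13 for the histones. Fewer cells in S phase may account for the fall against LiCl, where S phase genes had a median of -0.319. Against Li4Gy the S phase median was 0.00324, and -0.0350 without Li4Gy replicate 2, and neither value reached the fall set for this cause. Against LiCl the S phase medians were -0.327 for Li4Gy and -0.319 for Li8Gy, while the histone medians were -0.50 and -1.13. Without Li4Gy replicate 2 the Li4Gy histone median was -0.73. The further histone fall in Li8Gy was thus not matched by the S phase list. The explanation was left open because 1 of the S phase medians against Li4Gy lay below 0. A lower yield of RNAs that lack a poly(A) tail could have added to both, with medians of -0.191 and -0.157 over 227 such RNAs. Neither median reached the fall set in advance for this cause. Against Li4Gy the median was -0.105 without Li4Gy replicate 2, and a lower yield was not settled.

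Regrouping the arrays, set before the results were seen, gave a count of genes as large in 1 of 10 splits for each comparison, the real one, with 31 against at most 6 in any other split, and 2733, 1387 and 4542 against 0. For lists the numbers were 8 against 7, 7 against 6 and 9 against 6, again 1 of 10 splits, and 11 against 12 for Li4Gy against 4Gy, where 2 of 10 splits were as large. With 10 splits these are too few for a share under 0.05. The overall comparison of 4 groups gave 8627 genes, a count that was reached in 1 of 100 regroupings, the real one. The highest other was 3948, so chance alone is not likely to explain it. Except for Li8Gy against Li4Gy, regrouping also broke up the slides, so these counts could not tell group from slide.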

How the results depend on the processing

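Alternatives were fixed before the data were examined, and the cause of a change was not tested unless named. Of 2002 gene list values 149 were weaker, 33 stronger and 6 reversed, and of 5406 named gene values 1138 were weaker, 20 stronger and 6 reversed. Signal over background limits what can be said of dim genes, and in the lowest 10% of signal the median change was -1.21 for Li4Gy against 4Gy. In the order Li8Gy against Li4Gy, Li4Gy against LiCl, Li8Gy against LiCl and Li4Gy against 4Gy, leaving out single arrays of the compared groups gave 6 to 151, 1048 to 3027, 574 to 966 and 2061 to 4877 genes and 5 to 9, 5 to 8, 6 to 9 and 11 to 12 lists.

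For Li8Gy against Li4Gy the counts without Li4Gy replicates 1, 2 and 3 were 151, 6 and 12, and without the Li8Gy replicates 9, 8 and 7. For Li4Gy against LiCl they were 1048, 1472 and 1753 without the LiCl replicates and 1539 without Li4Gy replicate 2. For Li8Gy against LiCl they were 574 and 743 without LiCl replicates 1 and 3, and 755, 642 and 634 without the Li8Gy replicates. For Li4Gy against 4Gy they were 2061 and 2710 without 4Gy replicates 1 and 3.

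Median centring gave 11 genes for Li8Gy against Li4Gy, 5257 and 11 lists for Li4Gy against LiCl, 12916 for Li4Gy against 4Gy and 16061 in the overall comparison of 4 groups. It also turned VCAN to 0.145 in Li4Gy against 4Gy. Without the filter on dim probes 3, 891 and 495 genes were called in the first 3 comparisons, and 5 lists in the last. With genes well above background on all 12 arrays the counts were 50 genes and 4 lists for Li8Gy against Li4Gy and 2978 genes and 5 lists for Li4Gy against 4Gy. Trend and robust moderation gave 51 genes and array weights 72 for Li8Gy against Li4Gy, with a weight of 0.253 for Li4Gy replicate 2. Fits on only the compared groups called 0, 32 and 328 genes in the first 3 comparisons. At least 2-fold changes numbered 655, 281 and 2074 in the last 3.

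Normexp background correction with quantile normalization, and quantile normalization alone, each gave 5 lists for Li8Gy against Li4Gy and 0 for Li4Gy against 4Gy, with 2721 and 2901 genes in the latter. They turned the ribosomal protein list to 0.0756 and 0.0587 in Li8Gy against Li4Gy and to -0.0134 and -0.0212 in Li4Gy against 4Gy. In the latter they also turned the G1/S and S phase list to -0.0541 and -0.0510 and RPS2 to -0.0218 and -0.0584, and normexp turned PRDX1 to -0.00549. The mean over probes turned NKD2 to -0.0345 and BMF to -0.00692. Fry called 2 lists for Li8Gy against Li4Gy, and an estimated correlation 0 in all 4 comparisons. The series matrix gave 31, 2673, 1343 and 4508 genes.

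Replicate numbers were tried as a block, because the labels do not state a pairing. Over 18 pairs of arrays with a shared number the correlation of residuals ran from -0.0643 to 0.201, with 2 above 0.1, and the own number was highest in 6, so no pairing was assumed. With the block 21, 2207, 1060 and 4115 genes and 8, 6, 8 and 11 lists were called, and 7835 genes in the overall comparison of 4 groups. Slide as a block gave 31 genes for Li8Gy against Li4Gy, a result that was fixed in advance. Slides 1 and 2 each held 1 group, so that this fit is the same model as the main one. Its values are counted in the totals above and could not differ. The slide block was not run for the other comparisons and the F-test, where slide and group coincide. The F-test was not run with only 2 groups.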

Other observations

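Levels of some stress genes in the group without lithium could be set beside those of the other groups, although 4Gy and LiCl were not compared by a test. CHAC1 had a level of 0.75 ± 0.08 in LiCl, 1.48 ± 0.08 in 4Gy, 1.70 ± 0.19 in Li4Gy and 2.18 ± 0.09 in Li8Gy, and JDP2 had 0.65 ± 0.17 in 4Gy. Between Li4Gy and 4Gy results were mixed. JDP2 at 0.27 (adjusted p = 0.222), CHAC1 at 0.22 (adjusted p = 0.188), ASNS at 0.18 (adjusted p = 0.171) and PSAT1 at 0.03 (adjusted p = 0.867) did not pass, while the serine synthesis gene PHGDH rose by 0.48 (adjusted p = 0.0199) and the amino acid transporter subunit gene SLC3A2 by 0.41 (adjusted p = 0.0334, and 0.36 with adjusted p = 0.0699 without Li4Gy replicate 2). The transcription factor gene ATF4, looked up after the values were seen, was bright in all groups, from 8.28 ± 0.04 in 4Gy to 8.66 ± 0.17 in Li8Gy.

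Other genes looked up after the values were seen were CDKN1A, a p53 target that was well above background on 1 array each of Li4Gy and Li8Gy, and MYC, at 7.48 ± 0.13 in 4Gy and 7.75 ± 0.23 in Li8Gy. GSK3B, the kinase that lithium inhibits, had 1.98 ± 0.11 in LiCl and 1.31 ± 0.24 in 4Gy. LiCl and 4Gy differ in lithium, radiation and slide and were not compared by a test, so no effect of lithium can be read from this. Non-coding or unnamed genes made up 14 of the 21 falls of Li8Gy against Li4Gy and 328 of the 752 rises of Li8Gy against LiCl. Of all 22007 tested genes 13961 were protein coding. Neither these counts nor those of the other comparisons were tested against that share. The first principal component of the arrays held 52.8% of the variance and the second 8.27%.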
